A study of Mus musculus with 19 samples.

How the data were processed

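Liver RNA of 19 mice aged 10 months was measured on 1-colour Illumina mouse BeadChips, with 1 array per animal ID and biotin-labelled amplified RNA, per the labels' protocols. The groups were WT placebo (n = 8), KO placebo (n = 6) and KO SAMe (n = 5), taken from the genotype and treatment in the labels. The sex of the mice, the BeadChip each array lay on and the scanner software are not given in the sources used here.

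The authors deposited a raw table with a mean bead intensity for each of 45281 probes on each array, neither background corrected nor normalized between arrays, with a lowest value of 62.5. The same deposited table gives a detection p-value per probe and array, and control probes are not among its probes. The authors also deposited log2 values for 17592 probes. Recomputing them from the raw table showed that these are the probes with a detection p under 0.01 on at least 1 array, as log2 of the raw signal and quantile normalized, with every array median at 6.56, and the largest difference from the deposited values after rounding was 0. They were used as an alternative. All columns of values were mapped to samples by their names.

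Intensities were corrected with limma 3.58.1 in R 4.3.3 by the normexp model, with the background inferred from the detection p-values and an offset of 16. They were then quantile normalized and put on a log2 scale. Quantile normalization gives all arrays the same distribution, so a shift of most genes in 1 direction cannot be seen. Probes with a detection p under 0.05 on at least 5 arrays were kept, which left 14295. Gene names came from the platform annotation, in which 14737 probes had 1 gene symbol, 10 had several and 2845 of the probes in the authors' log2 table were unnamed here. Of the gene identifiers, 14715 matched the RefSeq table of assembly GRCm38.p6, and 0 symbols were updated. That table was used for names and for which genes neighbour each other, and no coordinates are given because the sources used here name no build. Each gene was represented by its probe with the highest mean over all arrays, and probes without 1 symbol were kept by themselves, which gave 8529 named genes and 2302 unnamed probes. For 2594 genes more than 1 probe passed the filter, and where the changes of a named gene's probes differed by over 1.5 times they are given beside it. Where a called gene was detected on under 50% of the arrays of a group, its fold is a lower bound, a limit of 50% chosen after the data were seen. That bound sets the brighter group's mean against the mean of the higher of the dim probe's own value and the lowest detected signal on each array. Of the genes named in lists, Plin4, Chac1 and Ntrk2 were detected on 7 and Mvk on 6 of 8 WT arrays, Cidec on 4 of 5 KO SAMe arrays, and Cox7b and Cyp2c55 on 4 and Cela2a on 5 of 6 KO placebo arrays.

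The 3 comparisons were made in 1 limma fit (lmFit and eBayes, two-sided) over all 19 arrays, so that the groups shared 1 estimate of the spread, with a Benjamini-Hochberg adjusted p under 0.05. Values in parentheses after a gene are log2 changes, SE is the standard error of the fit and SD the spread between arrays. The design, the alternatives and 39 gene lists with 1093 members in all were fixed before the data were examined. Of these lists 36 had at least 5 measured members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and 713 list members were measured. Lists share members, and the counts of genes in a list were also adjusted over the list alone. Camera with a correlation estimated from the arrays and fry were alternatives. The genes named were Mat1a and, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups of arrays did not overlap and which had a proper gene symbol. From each list described, up to 4 members with the largest moderated t were named, including members that did not pass where fewer than 4 did. Of the genes tested, 1800, 882 and 644 past the threshold had groups of arrays that did not overlap in the 3 comparisons in the order given above, against 0.067%, 0.43% and 0.16% of all genes by chance.

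The fit was tested on simulated data with the same numbers of arrays and 10831 genes, of which 100 were changed by a log2 of 0.5 and 100 by 1. It called 68% and 98% of them for KO against WT placebo, 54% and 95% for KO SAMe against KO placebo, and 62% and 96% for KO SAMe against WT placebo, with 7, 13 and 11 unchanged genes called. A simulated list of 20 moved genes was called in each comparison and 0 of 35 unmoved lists were. The simulated genes varied independently, so this does not show how often camera at the preset correlation calls unmoved lists of correlated genes. The male-biased list, for example, had an estimated correlation of 0.4.

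Alternatives changed 1 choice at a time, except that normexp without controls also set the offset to 50 and the authors' log2 values have no background correction and hold fewer probes. The choices were the background correction, the normalization, the authors' log2 values, the filter, the rule for genes with several probes, the arrays in the fit, array weights, the ID letter as a random block (duplicateCorrelation, with statmod 1.5.0) or a fixed term, the threshold, the prior variance, the set test and leaving out each array. After the data were seen, scaling to the median of the probes past the filter, counting named genes alone and the background set (as a block, low arrays alone, high arrays alone) were added. For comparisons that share arrays, chance overlap was simulated with genes drawn independently, and the shared arrays were split.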

Results

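Gene expression was measured in the livers of 19 mice aged 10 months on Illumina BeadChips, single-colour arrays that read labelled RNA with gene-specific probes attached to beads, with 1 array per animal. The mice were wild type (WT) or lacked Mat1a (KO), the gene for the liver enzyme that makes S-adenosylmethionine (SAMe), the methyl donor of most methylation reactions. There were 8 WT livers from placebo-treated mice, 6 KO livers from placebo-treated mice and 5 KO livers from mice given SAMe, with a treatment of 8 weeks. The labels give no SAMe-treated WT group, so an effect of SAMe that depends on genotype could not be tested. Of 45281 probes, between 25.5% and 31.8% were detected per array, and the number of arrays limits the precision of every value. The 10831 genes and unnamed probes that passed the detection filter are called genes below when they are counted.

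**Figure D1:**
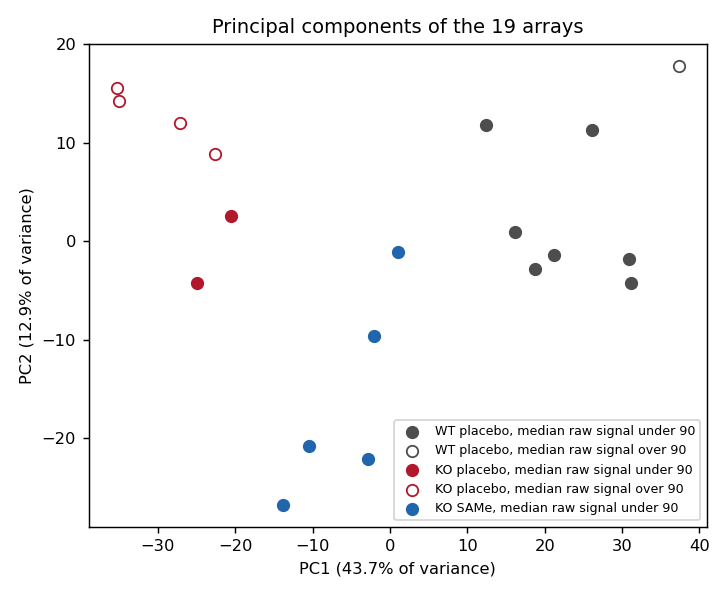
First against second principal component (PC1 and PC2, in units of the component score) of log2 intensities, with 1 point per array. Open points mark the 5 arrays with a median raw signal above 90. On PC1, which held 43.7% of the variance, WT arrays lay between 12.4 and 37.3, KO SAMe arrays between -13.8 and 1, and KO placebo arrays between -35.3 and -20.6.

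The arrays formed 2 sets by background, of which the labels say nothing. In 5 arrays the median raw signal was between 93.6 and 100, and in 14 it was between 75.1 and 85.8. The 5 brighter arrays were 4 of the 6 KO placebo livers and 1 of the 8 WT livers, and no KO SAMe array was among them. The total counts of genes and the counts of genes in each list called are therefore also given with the background set as a block and within the low-background set. The 4 brighter KO placebo arrays were those with letter J at the end of the animal ID, and the other 2 had letter G. Within KO placebo livers the background set and the ID letter are thus the same split, and a fit by one also changes the other. Arrays of the same group correlated with each other across genes between 0.9659 and 0.9904, so no array was a copy of another of its group.

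Mat1a itself was lower in both KO groups. Its log2 intensity was 12.12 ± 0.14 (SD, n = 8) in WT livers, 9.52 ± 0.31 (SD, n = 6) in KO placebo livers and 9.64 ± 0.12 (SD, n = 5) in KO SAMe livers. The log2 change against WT was -2.59 (SE 0.11, limma adjusted p = 2.6e-13) in KO placebo livers and -2.47 (SE 0.12, adjusted p = 1.3e-12) in KO SAMe livers, with every KO array below every WT array. The change between KO SAMe and KO placebo livers was 0.12 (adjusted p = 0.57), and its sign turned under 2 alternative settings. Mat1a was read by 1 probe, which was detected on all 19 arrays. Whether that probe lies in the deleted part of the gene is not given in the sources used here, so the signal left in KO livers does not measure remaining enzyme transcript.

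The comparison of KO with WT placebo livers addresses what the missing gene changes in the liver. The largest rises were in Cyp2b9 and Cyp2b13, cytochromes P450 that mouse liver expresses mainly in females. Cyp2b9 was at least 67.2-fold higher (adjusted p = 3.5e-16) and Cyp2b13 at least 31.3-fold higher, being detected on 1 and 0 of 8 WT arrays and on all 6 KO arrays. Lcn2, an iron-carrier-binding protein of the acute phase response, was 14.5-fold higher, and the metallothionein gene Mt1 was 11.5-fold higher. The protease gene Ctse was 9.69-fold, the water channel gene Aqp4 8.23-fold and the acute phase gene Saa1 8.14-fold higher, while the 2 probes of Saa1 gave log2 changes of 1.46 and 3.03. Asns, which codes for asparagine synthetase, was at least 6.76-fold higher by its brighter probe and was detected on no WT array, and its 2 probes gave log2 changes of 2.97 and 1.89. The largest fall was in Hsd3b5, a steroid dehydrogenase gene that mouse liver expresses mainly in males, which was 41-fold lower (log2 change -5.36, SE 0.61, adjusted p = 7e-07). Serpina1e, a member of the alpha-1-antitrypsin family, was 6.06-fold lower, and Angptl8, which codes for a regulator of lipoprotein lipase, was 5.78-fold lower. The major urinary protein gene Mup5 was 5.32-fold lower by its brighter probe, and its 2 probes gave log2 changes of -2.41 and -0.66. Fam25c and the proteasome subunit gene Psmb5 were 7.92-fold and 7.13-fold lower, and the transcription factor gene Cebpe was at least 4.87-fold lower, being detected on 1 of 6 KO arrays. These last 3 genes lie on chromosome 14 among the 100 measured genes nearest to Mat1a. Lcn2 and Aqp4 were each detected on 5 and Ctse on 7 of 8 WT arrays, and Fam25c on 5 and Psmb5 on 4 of 6 KO arrays. Probes of Cyp2b, Mup, Gstp and Serpina1 genes can also bind near-identical relatives, so values for single members of these families are uncertain.

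**Figure D2:**
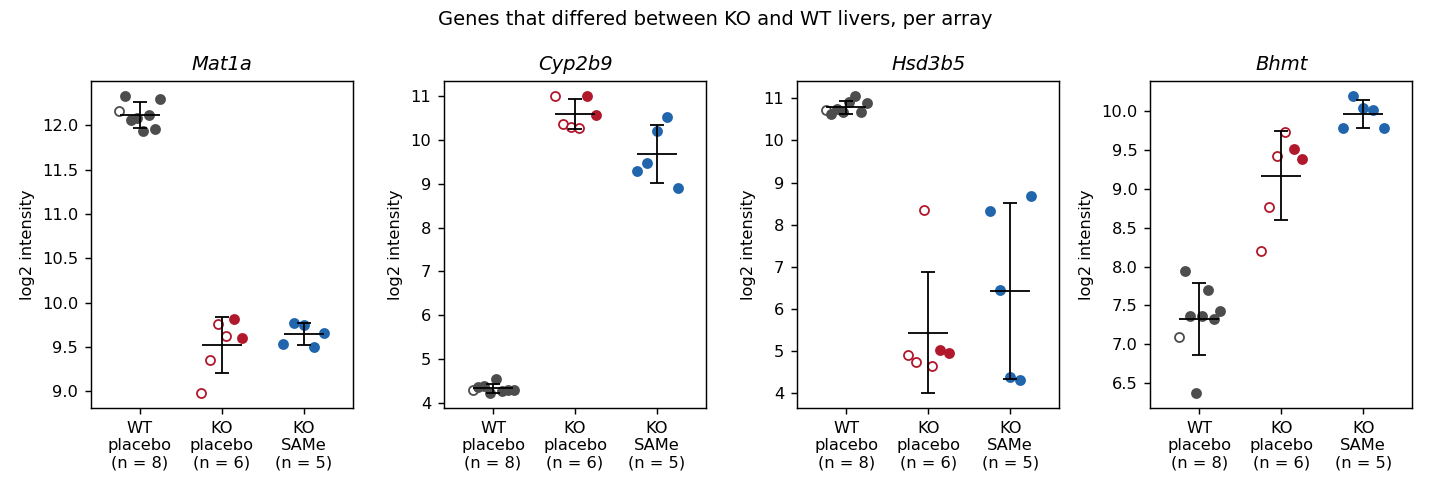
Log2 intensity of Mat1a, Cyp2b9, Hsd3b5 and Bhmt on each array by group (n = 8, 6 and 5). Open points are arrays with a median raw signal above 90, horizontal lines are means and error bars are 1 SD. In both KO groups Mat1a and Hsd3b5 lay below, and Cyp2b9 and Bhmt above, every WT array.

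Sex-biased and xenobiotic-handling genes moved in KO livers. Of 24 measured male-biased liver genes, 13 fell and 3 rose (the same counts adjusted over the list alone), with a median log2 change of -0.62. Besides Hsd3b5 these included Gstp1 (-1.68, with -1.30 and -0.93 at its other probes), Mup21 (-1.77) and Nudt7 (-0.74). The list had a camera adjusted p = 0.009, and an adjusted p = 0.51 with an estimated correlation. Of 12 female-biased genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), the risers being Cyp2b9, Cyp2b13, the steroid hydroxylase gene Cyp17a1 (2.40) and Ntrk2 (2.11). Its camera adjusted p = 0.02, and the adjusted p = 0.47 with an estimated correlation. Among 33 genes of xenobiotic cytochromes and conjugation 17 rose and 5 fell (17 and 6 adjusted over the list alone), including rises of the flavin monooxygenase gene Fmo1 (1.32, with 0.65 at another probe) and of Cyp2d26 (1.39). That list had a camera adjusted p = 0.0022, and an adjusted p = 0.47 with an estimated correlation. With the background set as a block and within the low-background set, 12 and 9 male-biased genes fell and 3 and 1 rose, 4 and 4 female-biased genes rose and none fell, and 18 and 11 xenobiotic genes rose and 4 and 2 fell.

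The methionine cycle and cholesterol synthesis lists were called, with more genes higher than lower. Of 22 genes of the methionine cycle and transmethylation, 12 rose and 4 fell (12 and 4 adjusted over the list alone). Mat1a, the targeted gene, is itself a member and among those that fell. Bhmt, which codes for the enzyme that remethylates homocysteine with betaine, rose by a log2 change of 1.85, and Dmgdh and Chdh of the choline oxidation pathway rose by 1.65 and 1.15. Chdh also lies near Mat1a on chromosome 14. The list had a camera adjusted p = 0.023, and an adjusted p = 0.4 with an estimated correlation. Of 18 cholesterol synthesis genes and targets of their regulator SREBP2, 9 rose and 0 fell (9 and 0 adjusted over the list alone), among them Fdps (1.21), Dhcr7 (1.0) and Msmo1 (0.84). The camera adjusted p = 0.0097, and the adjusted p = 0.47 with an estimated correlation. After blocking on the background set and within the low-background set, 11 and 6 methionine cycle genes rose and 3 and 2 fell, and 6 and 6 cholesterol synthesis genes rose and none fell.

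Lipid storage genes rose in KO livers. Of 21 genes of lipid droplets and fatty acid uptake, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median log2 change of 0.56. The lipid droplet protein gene Cidec was at least 2.67-fold higher and detected on no WT array, Plin4 rose by 1.49, the lipoprotein lipase gene Lpl by 1.49 and Fitm1 by 0.96. Camera gave the list an adjusted p = 0.0031, and an adjusted p = 0.21 with an estimated correlation. Of 9 adipocyte markers 8 rose and 0 fell (8 and 0 adjusted over the list alone), including Cidea (at least 3.74-fold higher, detected on 1 of 8 WT arrays), with a camera adjusted p = 0.00057 and an adjusted p = 0.21 with an estimated correlation. The 2 lists share 6 measured genes, among them Cidec, Plin4, Lpl and Cidea. Genes of oxidative phosphorylation moved the other way, with 21 of 46 lower and 5 higher (23 and 5 adjusted over the list alone). Cox7b (-1.02), Ndufa4 (-0.57) and Ndufv2 (-0.52) fell, and Atp5d rose by 0.46. The camera adjusted p = 0.008, and the adjusted p = 0.47 with an estimated correlation. With the background set as a block 13 of its genes fell and 6 rose (camera adjusted p = 0.051), and within the low-background arrays 4 fell and 3 rose (camera adjusted p = 0.5), with a median of -0.06 against -0.22 over all arrays. In these 2 fits, 12 and 7 lipid droplet genes rose and 2 and 0 fell, and 8 and 7 adipocyte markers rose and none fell.

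Acute phase, stress and matrix lists were called as well. Of 28 acute phase genes 18 rose and 0 fell (18 and 0 adjusted over the list alone), led by Lcn2, Mt1, Saa1 and the protease inhibitor gene Serpina3n (1.47), with a camera adjusted p = 0.00015 and an adjusted p = 0.28 with an estimated correlation. Of 23 genes of endoplasmic reticulum stress and the amino acid response, 10 rose and 0 fell (10 and 0 adjusted over the list alone), including Asns, Creld2 (2.38), Chac1 (1.85) and the chaperone gene Hsp90b1 (1.24). Its camera adjusted p = 0.0016, and the adjusted p = 0.4 with an estimated correlation. Of 19 immediate early and heat shock genes 8 rose and 0 fell (8 and 0 adjusted over the list alone), among them Hsph1 (1.99), Hspb1 (1.35) and Klf6 (1.23), with a camera adjusted p = 0.011 and an adjusted p = 0.47 with an estimated correlation. Hsph1 and Hspb1 code for chaperones and Klf6 for a transcription factor, and the list median of 0.41 turned to -0.04 with the ID letter as a term. Of 28 extracellular matrix and stellate cell genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), including the basement membrane collagen genes Col4a2 (1.89) and Col4a1 (1.49), and Timp2 (0.97). That list had a camera adjusted p = 0.0016, and an adjusted p = 0.47 with an estimated correlation. Under the background block and in the low-background arrays, 13 and 6 acute phase genes, 8 and 6 endoplasmic reticulum stress genes, 6 and 7 immediate early and heat shock genes and 10 and 5 matrix genes rose, and none fell.

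Keratin genes led the cholangiocyte and progenitor list, in which 6 of 13 genes rose and 1 fell (6 and 1 adjusted over the list alone). Krt23, Krt8 and Krt18 rose by 1.88, 1.66 and 1.19, and hepatocytes also express Krt8 and Krt18. Camera gave the list an adjusted p = 0.033, and an adjusted p = 0.47 with an estimated correlation. Of 24 oncofetal and liver tumour markers 8 rose and 2 fell (8 and 2 adjusted over the list alone). Spink1, a trypsin inhibitor gene, was at least 6.79-fold higher (detected on 2 of 8 WT arrays), and Anxa2 rose by 1.60 and Robo1 by 1.41, with a camera adjusted p = 0.033 and an adjusted p = 0.47 with an estimated correlation. After blocking on the background set its camera adjusted p was 0.051, and its median of 0.13 turned to -0.09 when arrays were scaled to the median of the probes past the filter. When the background set was a block and when only low-background arrays were used, 6 and 3 cholangiocyte genes rose and 1 and 0 fell, and 8 and 7 oncofetal markers rose and 2 and 1 fell. The other 22 lists tested were not called in this comparison. They included hepatocyte identity (8 rose and 4 fell of 34, camera adjusted p = 0.13), macrophages and monocytes (5 rose and 2 fell of 28, camera adjusted p = 0.13) and cell proliferation (0 rose and 7 fell of 19, camera adjusted p = 0.076).

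In all, 4359 of 10831 genes differed between KO and WT placebo livers at a limma adjusted p under 0.05, 2148 higher and 2211 lower, and 569 of them by at least 2-fold (344 higher and 225 lower). When the background set was a block, 3926 genes differed (1969 higher and 1957 lower), 637 of them by at least 2-fold, and within the low-background set of 2 KO and 7 WT arrays 1979 (1005 and 974), 399 of them by at least 2-fold. The high-background set of 4 KO arrays and 1 WT array gave 3305 (1542 and 1763), a fit that assumes that the lone WT array varies like the KO arrays, so it does not show that the difference holds in that set. The balance of directions rests on quantile normalization, since scaling each array to its median gave 4012 higher and 988 lower and scaling to the median of the probes past the filter gave 1786 higher and 4589 lower. Those scalings moved the median log2 change of all genes to 0.18 and to -0.20. With the letter that ends the animal ID as a term, 54 genes differed, because no letter was shared by KO placebo and WT mice.

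**Figure D3:**
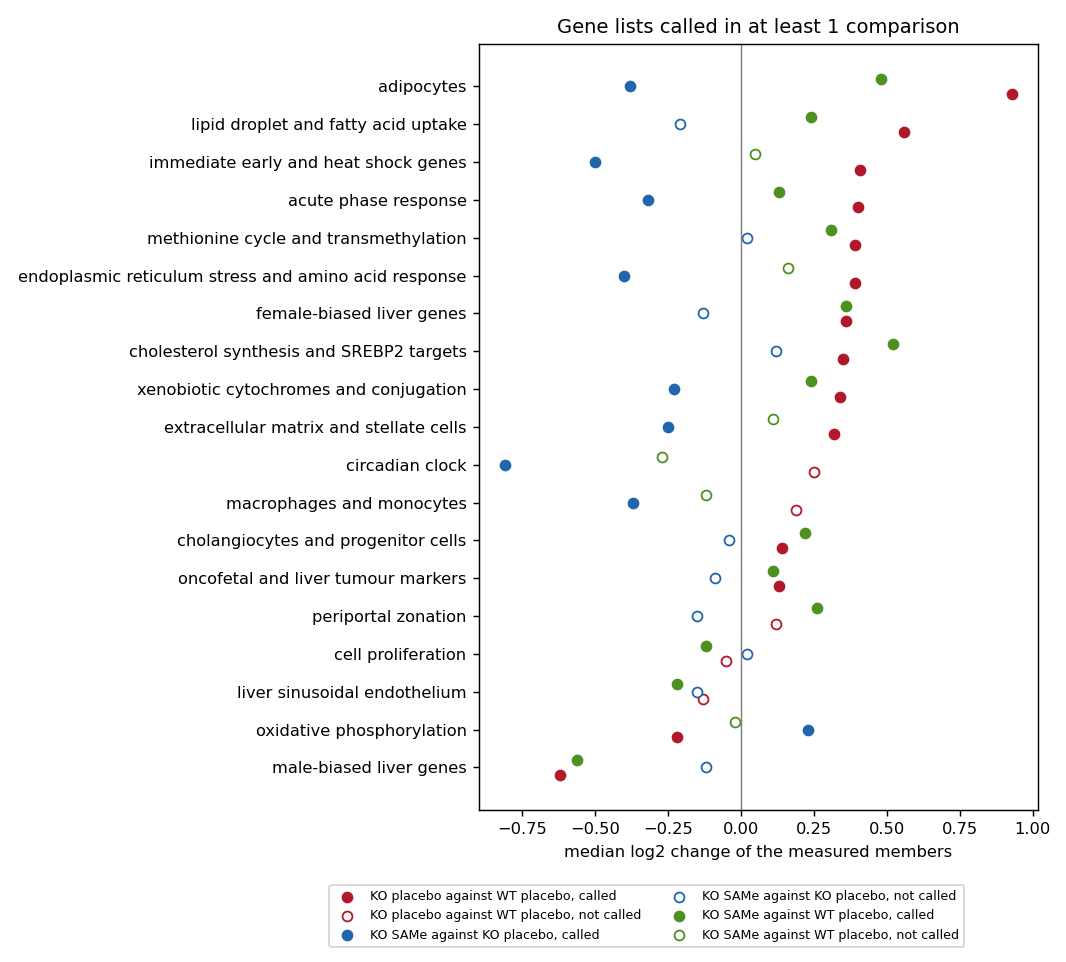
Median log2 change of the measured members (horizontal axis) for each gene list called in at least 1 comparison, with filled points where camera called the list and open points where it did not. The adipocyte list had medians of 0.93 in KO against WT placebo livers, -0.38 in KO SAMe against KO placebo livers and 0.48 in KO SAMe against WT livers, and the male-biased list -0.62, -0.12 and -0.56.

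The comparison of KO SAMe with KO placebo livers addresses the effect of SAMe in mice without Mat1a. Falls were larger than rises. The transcription factor gene Cebpb fell by a log2 change of 1.73 (3.31-fold, SE 0.27, adjusted p = 0.00043), and the chaperone genes Creld2, Hspb1 and Hspd1 were 3.17-fold, 3.12-fold and 2.59-fold lower. Slc25a25, a mitochondrial carrier gene, was 3.09-fold lower, the acute phase genes Saa4 and Lcn2 were 2.99-fold and 2.64-fold lower, and the clock regulator gene Bhlhe40 was 2.96-fold lower. Blocking on the background set ended the calls of Saa4 (-1.33, adjusted p = 0.12), Lcn2 (-1.19, adjusted p = 0.068) and Bhlhe40 (-1.02, adjusted p = 0.081), and without KO SAMe replicate 2 the change of Saa4 was -0.98. The largest rise was in the elastase gene Cela2a, also a marker of pancreatic acinar cells (2.59-fold, log2 change 1.37, SE 0.21, adjusted p = 0.00041). Dclk3, Alkbh7, Albfm1, Cldn5, Clec2d and Arsg were between 2.2-fold and 2.4-fold higher, and so was Mrnip (1.22), whose change with the block was 0.54 (adjusted p = 0.094).

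**Figure D4:**
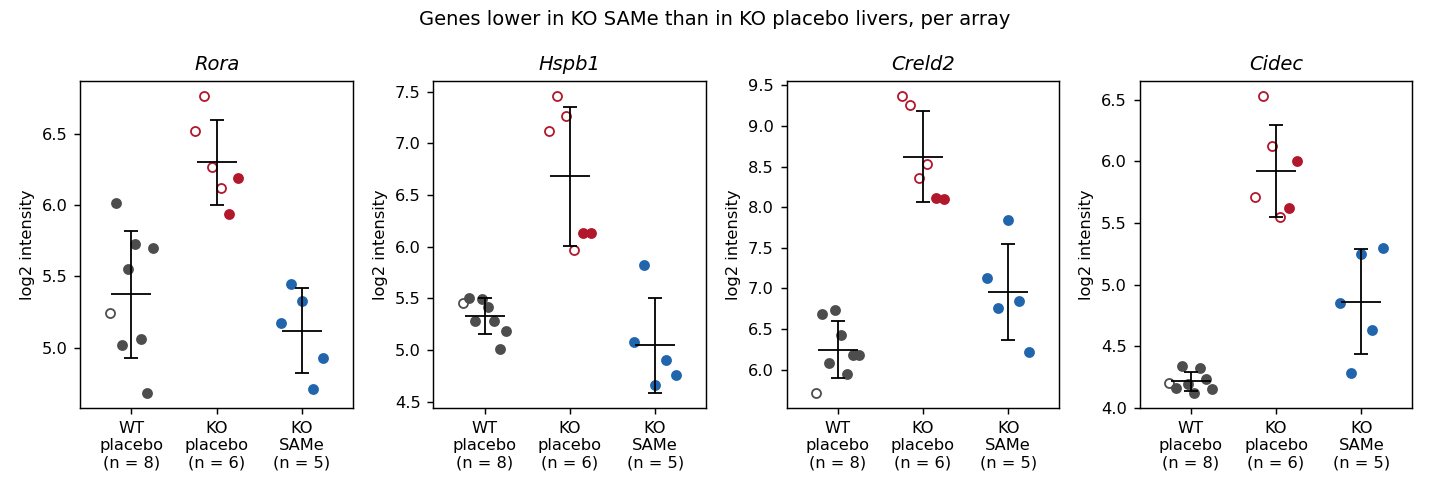
Log2 intensity of Rora, Hspb1, Creld2 and Cidec on each array by group (n = 8, 6 and 5). Open points are arrays with a median raw signal above 90, horizontal lines are means and error bars are 1 SD. The change from KO placebo to KO SAMe livers was -1.18 for Rora, -1.64 for Hspb1, -1.66 for Creld2 and -1.06 for Cidec.

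Clock and stress lists were called, with genes lower in KO SAMe livers. Time of day and feeding at collection did not enter the fits, so their effects cannot be told apart from that of treatment. Of 14 circadian clock genes 7 fell and 0 rose (8 and 0 adjusted over the list alone), with a median log2 change of -0.81. They included Bhlhe40 (-1.57), the nuclear receptor gene Rora (-1.18), the glucocorticoid-induced gene Tsc22d3 (-1.04, with -0.46 and -0.29 at its other probes) and Per2 (-0.87). The camera adjusted p = 0.00015, and the adjusted p = 0.2 with an estimated correlation. When the background set was a block, Rora alone of the clock genes fell, with Per2 at -0.53 (adjusted p = 0.084) and Tsc22d3 at -0.65 (adjusted p = 0.13), and the list had a median of -0.52 and a camera adjusted p = 0.0067, and within the low-background set no clock gene passed, while the list had a median of -0.48 and a camera adjusted p = 0.0088. Of 19 immediate early and heat shock genes 4 fell and 0 rose (11 and 0 adjusted over the list alone), namely Hspb1 (-1.64), Hsph1 (-1.55), Klf6 (-0.62) and Hspa1a (at least 1.32-fold lower, detected on 2 of 5 KO SAMe arrays), with a camera adjusted p = 0.00022 and an adjusted p = 0.43 with an estimated correlation. The call of Klf6 ended with the background set as a block (-0.35, adjusted p = 0.33) and when any of 4 single arrays was left out, and that of Hspa1a without KO SAMe replicate 4. Of 23 genes of endoplasmic reticulum stress and the amino acid response 5 fell and 0 rose (5 and 0 adjusted over the list alone), including Creld2 (-1.66), Dnajb9 (-1.20, with -0.56 at another probe), Hsp90b1 (-1.08) and Herpud1 (-0.54, with -1.14 at another probe). Its camera adjusted p = 0.00096, and the adjusted p = 0.43 with an estimated correlation. After blocking on the background set that list had a camera adjusted p = 0.065 and a median of -0.15 against -0.40, and within the low-background set an adjusted p = 0.1. The block ended the calls of Dnajb9 (-0.60, adjusted p = 0.21), Hsp90b1 (-0.62, adjusted p = 0.15) and Herpud1 (-0.40, adjusted p = 0.078). In these 2 fits 1 and 0 genes of the list fell, and 3 and 1 immediate early and heat shock genes fell, with camera adjusted p = 0.0056 and 2.7e-05 for the latter list.

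Acute phase, macrophage and matrix lists were called with genes lower as well. Of 28 acute phase genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), among them Saa4 (-1.58), Lcn2 (-1.40), Serpina3n (-0.77) and Crp (-0.49). Camera gave the list an adjusted p = 0.0027, and an adjusted p = 0.43 with an estimated correlation. When the background set was a block, the camera adjusted p was 0.065, and within the low-background set it was 0.33. Of 28 macrophage and monocyte genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), these being the antigen presentation genes Cd74 (-1.30, with -1.51 and -0.67 at its other probes) and H2-Aa (at least 1.23-fold lower, and detected on 0 of 5 KO SAMe arrays), the complement gene C1qc (-0.91) and Mpeg1 (-0.76). The list had a camera adjusted p = 0.00059, and an adjusted p = 0.61 with an estimated correlation. The calls of Mpeg1 and C1qc each ended with the background set as a block (-0.32, adjusted p = 0.46, and -1.12, adjusted p = 0.054) and when any of several single arrays was left out, and that of Serpina3n without KO SAMe replicate 4. Of 28 extracellular matrix and stellate cell genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), including Col4a2 (-1.18), Col4a1 (-0.77), Colec11 (-0.75) and Vim (at least 1.37-fold lower, detected on 2 of 5 KO SAMe arrays). The camera adjusted p = 0.0024, and the adjusted p = 0.61 with an estimated correlation. After blocking on the background set and within the low-background set, 2 and 0 acute phase genes, 3 and 0 macrophage genes (Cd74, H2-Aa and a gene not called over all arrays) and 3 and 1 matrix genes fell, and none rose. The macrophage list had a camera adjusted p = 0.0056 and 0.011 in these 2 fits, and the matrix list 0.0056 and 0.012. Vim had a change of -0.44 with the block (adjusted p = 0.059).

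Genes of oxidative phosphorylation moved up, with 14 of 46 higher and 1 lower (15 and 1 adjusted over the list alone). Cox7b (0.97), Ndufa7 (0.72) and Ndufb8 (0.56) rose, and Ndufs3 fell by 0.53. Camera gave the list an adjusted p = 0.00059, and an adjusted p = 0.61 with an estimated correlation. Within the low-background set the p at the preset correlation was 0.33, with a median of 0.07 against 0.23. Of 9 adipocyte markers 3 fell and 0 rose (4 and 1 adjusted over the list alone), namely Cidec (-1.06), Plin4 (-1.01) and the carbonic anhydrase gene Car3 (-0.85), while Lpl had a change of 0.77 (adjusted p = 0.066). That list had a camera adjusted p = 0.016, and an adjusted p = 0.43 with an estimated correlation. Of 33 xenobiotic genes 6 fell and 2 rose (6 and 2 adjusted over the list alone), with falls in Cyp2d26 (-1.12), Fmo5 (-1.11) and Cyp2b9 (-0.90) and a rise in Cyp2c55 (0.78). Its camera adjusted p = 0.038, and the adjusted p = 0.61 with an estimated correlation. With the background set as a block the p at the preset correlation was 0.38. In that fit 6 oxidative phosphorylation genes rose and 2 fell, 4 adipocyte markers fell and 3 xenobiotic genes fell and 1 rose, and within the low-background set 3 adipocyte markers fell and no gene of the other 2 lists passed. The adipocyte list had a camera adjusted p = 0.00076 with the block and 1e-05 within the low-background set. The lipid droplet list, with 5 genes lower and 0 higher of 21 (5 and 1 adjusted over the list alone), had a camera adjusted p = 0.076, an adjusted p = 0.43 with an estimated correlation and an adjusted p = 0.014 with the background set as a block. The methionine cycle list was not called, with 2 genes higher and 0 lower of 22 (camera adjusted p = 0.99). The female-biased list, with 1 of 12 genes lower (camera adjusted p = 0.27), and the male-biased list (camera adjusted p = 0.42, median -0.12) were not called either.

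In all, 2000 genes differed between KO SAMe and KO placebo livers, 1167 higher and 833 lower, and 107 by at least 2-fold (23 higher and 84 lower). After blocking on the background set 1003 genes differed (521 higher and 482 lower), 89 of them by at least 2-fold. Within the low-background set, which holds 2 KO placebo and 5 KO SAMe arrays, 76 differed (35 and 41), 15 of them by at least 2-fold, and 69 of the 76 were also called over all arrays. Of the 47 genes named as changed between these groups, 33 kept their call with the block and 6 within the low-background set. All 47 kept their direction in both fits, with a median of 0.9 and 0.79 times their log2 change over all arrays. The largest rises and falls were named because the 2 groups of arrays did not overlap, which fixes their direction within the low-background set. The others were chosen by their moderated t over these same arrays, so the kept direction gives no separate support. Within the low-background set Cela2a had 1.35, Cebpb -1.38 (adjusted p = 0.073) and Car3 -0.86 (adjusted p = 0.082), so with 2 KO placebo arrays a lost call does not show that a change is absent. With the ID letter as a term 1 gene differed, which was not called otherwise, and the letter G alone occurs in both groups. Scaling each array to its median gave 202 higher and 3153 lower genes, and scaling to the median of the probes past the filter gave 2608 and 884, with medians over all genes of -0.21 and 0.16.

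Most genes called between KO SAMe and KO placebo livers (81%) were also called between the genotypes, nearly all with the opposite sign, though treatment and ID letter cannot be told apart for them and a part from the background set stays open. Of the 4359 genotype genes, 1601 (36.7%) were called in the opposite direction between KO SAMe and KO placebo livers, here termed called back, and 18 in the same direction. Of these 1601, 701 were higher in KO placebo than in WT livers and lower in KO SAMe than in KO placebo livers, and 900 were lower and then higher, against 165.2 and 238.2 for independent lists of the same sizes. Both comparisons use the KO placebo arrays, which gives opposite signs by itself. In 50 simulations without an effect of SAMe, the highest count was 1. Their genes varied independently, so few could be called between KO SAMe and KO placebo livers, and a low count was set in advance. In as many without an effect in any group the median covariance of the log2 changes was -0.0114, against -0.114 observed. These simulations hold no difference between the background sets and no variation shared by many genes, and so exclude nothing about either. A simulated difference with an SD of 0.5 between the sets alone gave 36 called genes for KO SAMe against KO placebo livers without the block and 0 with it. That SD was set and not estimated from the arrays, and the genes varied independently. The noise was the spread within groups, which already holds any real difference between the sets. The count of 36 therefore does not measure how many calls the background set could give in these data. With the KO placebo arrays split into separate sets of 3 for the 2 comparisons, in 20 splits, a median of 487 genes (38 to 1038) was called back. The slope of the SAMe change on the genotype change was then -0.39 (-0.47 to -0.31), with opposite signs for 85.8% of genotype genes. Since 4 of the 6 KO placebo arrays have the high background and letter J, every set of 3 held at least 1 of them. These splits remove the shared arrays, but leave a difference of background or letter in both comparisons with opposite signs. When the background set was a block, 864 genes were called back, and within the low-background set 70. With the ID letter as a term 1 was called back.

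The comparison of KO SAMe with WT placebo livers addresses what remained different under treatment. Cyp2b9 was at least 36.1-fold higher (adjusted p = 3.1e-14), Cyp2b13 at least 16.8-fold and Spink1 at least 5.72-fold, being detected on 1, 0 and 2 of 8 WT arrays. Mt1 was 8.43-fold, Aqp4 7.81-fold, Bhmt 6.25-fold, the ADP-ribosyltransferase gene Parp16 6.03-fold and Lrtm1 5.83-fold higher. Hsd3b5 was 20.6-fold lower (log2 change -4.36, SE 0.65, adjusted p = 7.7e-05), with an SD of 2.09 among the 5 KO SAMe arrays, of which 3 detected it. Serpina1e was 9.94-fold, Fam25c 6.9-fold, Psmb5 6.61-fold (detected on 3 of 5 KO SAMe arrays) and the glutathione transferase gene Gstp1 4.37-fold lower by its brightest probe (its 3 probes gave log2 changes of -2.13, -1.65 and -0.93), and Cebpe was at least 4.73-fold lower and detected on no KO SAMe array. Ndrg2 was 4.37-fold lower by its brighter probe, while its 2 probes gave log2 changes of -2.13 and -0.18. Lrtm1, Fam25c, Psmb5, Cebpe and Ndrg2 are among the 100 measured genes nearest to Mat1a.

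**Figure D5:**
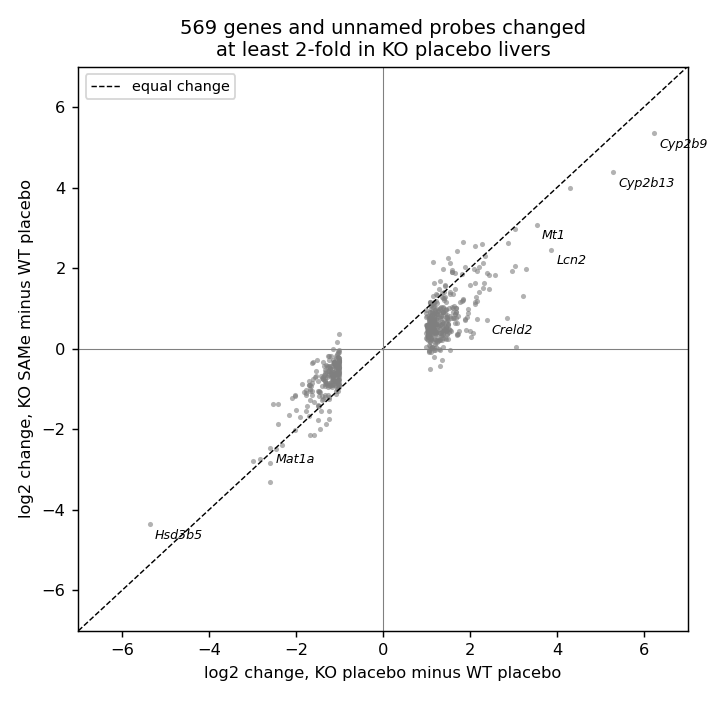
Log2 change against WT placebo livers in KO placebo (horizontal axis) and KO SAMe livers (vertical axis) for the 569 genes and unnamed probes changed at least 2-fold in KO placebo livers, with a dashed line of equal change. Cyp2b9 lay at 6.24 and 5.34, Hsd3b5 at -5.36 and -4.36, Mat1a at -2.59 and -2.47 and Lcn2 at 3.86 and 2.46. Both axes use the same WT arrays, which draws points toward the dashed line. The genes were chosen by their change on the horizontal axis, which by itself favours larger changes there than on the vertical axis.

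Methionine, cholesterol and sex-biased genes still differed from WT after SAMe. Of 22 methionine cycle genes 11 rose and 3 fell (12 and 3 adjusted over the list alone), with Bhmt at 2.64, Dmgdh at 1.87 and Chdh at 1.10, a camera adjusted p = 0.0061 and an adjusted p = 0.37 with an estimated correlation. The targeted gene Mat1a is again among those that fell. Of 18 cholesterol synthesis genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), among them Mvd (1.32), Dhcr7 (0.88), Msmo1 (0.74) and Mvk (0.73). Its camera adjusted p = 2.2e-06, and the adjusted p = 0.37 with an estimated correlation. Of 24 male-biased genes 12 fell and 1 rose (14 and 1 adjusted over the list alone), including Hsd3b5, Serpina1e, Gstp1 (-2.13) and the complement gene C9 (-1.15, with -1.01 and 0.10 at its other probes). The camera adjusted p = 2.2e-06, and the adjusted p = 0.37 with an estimated correlation. Of 12 female-biased genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Cyp17a1 at 1.89, Ntrk2 at 1.62, a camera adjusted p = 0.014 and an adjusted p = 0.37 with an estimated correlation. Under the background block and in the low-background arrays, 11 and 10 methionine cycle genes rose and 3 and 3 fell, 10 and 10 cholesterol synthesis genes rose and none fell, 13 and 12 male-biased genes fell and 1 and 1 rose, and 4 and 4 female-biased genes rose and 1 and 1 fell.

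Lipid, acute phase and keratin genes were called again. Of 21 lipid droplet genes 4 rose and 0 fell (7 and 1 adjusted over the list alone), with Lpl at 2.26, Fitm1 at 1.23 and Cidec at least 1.28-fold higher, a camera adjusted p = 0.031 and an adjusted p = 0.37 with an estimated correlation. Of 9 adipocyte markers 2 rose and 0 fell (3 and 0 adjusted over the list alone), namely Lpl and Cidec, while Cidea, detected on 1 of 8 WT arrays, had a change of 1.18 (adjusted p = 0.059) and Plin4 of 0.48 (adjusted p = 0.14). The list had a camera adjusted p = 0.011, and an adjusted p = 0.37 with an estimated correlation. Of 28 acute phase genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), with Mt1 at 3.08, Lcn2 at 2.46 and Saa1 at 2.06 (1.42 at its other probe), a camera adjusted p = 0.011 and an adjusted p = 0.37 with an estimated correlation. Of 13 cholangiocyte and progenitor genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with Krt23 at 2.03, Krt18 at 0.97 and Krt8 at 0.85, a camera adjusted p = 0.016 and an adjusted p = 0.37 with an estimated correlation. Of 24 oncofetal markers 8 rose and 0 fell (8 and 1 adjusted over the list alone), with Spink1 as above, Anxa2 at 1.36 and Robo1 at 1.25, a camera adjusted p = 0.019 and an adjusted p = 0.37 with an estimated correlation. Of 33 xenobiotic genes 7 rose and 2 fell (12 and 2 adjusted over the list alone), including a rise of Fmo1 (0.76) and a fall of Cyp2c29 (-0.65, a call that ended without KO SAMe replicate 2), with a camera adjusted p = 0.012 and an adjusted p = 0.37 with an estimated correlation. When the background set was a block and when only low-background arrays were used, 4 and 5 lipid droplet genes, 2 and 4 adipocyte markers, 9 and 7 acute phase genes, 5 and 5 cholangiocyte genes and 8 and 8 oncofetal markers rose and none fell, and 8 and 7 xenobiotic genes rose and 2 and 2 fell.

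The endothelial, periportal and proliferation lists were called in this comparison and not between KO and WT placebo livers, a difference that was not tested itself. Single genes of these lists also passed between KO and WT placebo livers. There 4 endothelial markers rose and 6 fell, 7 periportal genes rose and 1 fell, and 0 proliferation genes rose and 7 fell. The list calls therefore do not show changes that are new in KO SAMe livers. Of 21 markers of the liver sinusoidal endothelium 6 fell and 0 rose (7 and 0 adjusted over the list alone), among them Mrc1 (-0.70), Adgrl4 (-0.69), Clec4g (-0.62) and the scavenger receptor gene Stab1 (-0.32, with 0.07 at another probe). Its camera adjusted p = 0.022, and the adjusted p = 0.4 with an estimated correlation. Without KO SAMe replicate 2 the calls of Mrc1 and Clec4g ended, and the call of Stab1 ended without any of several other arrays. Of 18 periportal genes, expressed where blood enters the liver lobule, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with Cyp17a1 at 1.89, Aldh1b1 at 1.01, Hal at 0.57 and Igfals at 0.55. Camera gave the list an adjusted p = 0.039, and an adjusted p = 0.37 with an estimated correlation. Of 19 proliferation genes 2 fell and 0 rose (2 and 0 adjusted over the list alone), these being Tk1 (-1.18, with -0.39 and -0.16 at its other probes) and the centromere protein gene Cenpa (-1.04), while Tyms had a change of -0.41 (adjusted p = 0.059). That list had a camera adjusted p = 0.039, and an adjusted p = 0.4 with an estimated correlation. In the fit with the background block and in that of the low-background set, 6 and 5 endothelial markers and 2 and 2 proliferation genes fell and none rose, and 8 and 8 periportal genes rose and 0 and 1 fell.

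In all, 1904 genes differed between KO SAMe and WT placebo livers, 1028 higher and 876 lower, and 193 by at least 2-fold. Of the 4359 genotype genes, 1439 (33%) were still called in the same direction, against 203.9 higher and 178.8 lower for independent lists, and 1326 were both called back and no longer called against WT. In the fit with the block 1414 were still called and within the low-background set 903, of 3926 and 1979 genotype genes. Those both called back and no longer called against WT were 698 with the block and 58 within the low-background set. A gene no longer called has not been shown to equal WT. With separate sets of 4 WT arrays for the 2 comparisons, in 70 splits, the slope of the KO SAMe change on the KO placebo change was 0.52 (0.34 to 0.70), and a median of 604 genes (384 to 1179) was called in both. After blocking on the background set 1931 genes differed (1020 higher and 911 lower), 186 of them by at least 2-fold, and within the low-background set of 5 KO SAMe and 7 WT arrays 1612 (867 and 745), 179 of them by at least 2-fold. Without KO SAMe replicate 2 the count was 1213.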

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

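The tests of background correction, splits that keep the high-background arrays together, Eif2s3y, hepatocyte genes and the neighbours of Mat1a were chosen after the result was seen, and the tests on array subsets and ID letters and the other splits of the arrays before.

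Among 315 groups of values (105 genes and measures in 3 groups), 23 had 1 array whose gap to the nearest other array took up an unusually large share of the group's range. Chance alone gives about 1 in 20, or 15.8. WT replicate 1, which has the high background, had Car3 at 7.93 (others 8.99 to 9.54), Cd74 at 5.41 (6.47 to 7.41), Hsph1 at 7.61 (6.78 to 7.14), Mup5 at 10.68 (9.77 to 10.17) and Parp16 at 6.49 (5.27 to 5.84), all log2 intensities. WT replicate 7 had Arsg at 7.8 (6.47 to 7.07) and Cidea at 4.57 (4.14 to 4.31), WT replicate 4 Dmgdh at 4.75 (5.19 to 5.52), WT replicate 2 Lcn2 at 6.12 (4.27 to 5.04) and WT replicate 6 Tk1 at 8.21 (7.66 to 7.88). In KO placebo replicate 2 the acute phase genes Lcn2 and Saa1 stood at 10.05 (8.09 to 8.77) and 13.15 (10.74 to 11.59). KO placebo replicate 3 had Hsd3b5 at 8.35 (4.63 to 5.03) and Hspa1a at 4.32 (5.06 to 5.35), replicate 4 Msmo1 at 10.08 (9.33 to 9.56) and replicate 5 Cebpe at 4.5 (4.23 to 4.27) and Fdps at 10.78 (11.13 to 11.32). KO SAMe replicate 4 had Asns at 4.29 (6.37 to 7.01), Herpud1 at 11.24 (11.77 to 11.85) and Serpina1e at 6.86 (9.6 to 9.91). KO SAMe replicate 2 had Cox7b at 4.97 (5.51 to 5.71), Cyp2c29 at 4.64 (5.33 to 5.52) and Saa4 at 4.82 (7.21 to 8.15).

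The genes changed between KO SAMe and KO placebo livers may partly reflect the high background of 4 KO placebo arrays or the cohort that the ID letter could mark, besides the treatment. Among KO placebo arrays these sources cannot be told apart, since the 4 high-background arrays are those of letter J and the 2 low-background arrays those of letter G. A test that sets these 4 arrays against the others therefore bears on background and letter together. Background correction as the whole cause is argued against, since 91.8% of the called genes were called again without it. The background set as the whole cause is argued against too, since of the 21 splits that keep the 4 high-background arrays together in the group of 6 the real one gave 1838 genes and the highest other 333. A part stays open, since genes called between those 4 arrays and 3 KO SAMe arrays had a median slope of 0.44 (0.30 to 0.56 over 10 choices) in the 2 low-background KO placebo and the other 2 KO SAMe arrays, between the bounds of 0.2 and 0.5 set for a decision. Genes called between the other letters had a slope of 0.45 within letter G, where 1 KO SAMe array stands against 2 KO placebo arrays, too few to tell the treatment and the letter apart.

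In KO placebo against WT livers 13 of 24 male-biased genes fell and 3 rose, and 4 of 12 female-biased genes rose and 1 fell. Neither list was called by camera with an estimated correlation (adjusted p = 0.51 and 0.47). Females among the KO mice could be a source of these changes. The Y-linked gene Eif2s3y, the only 1 measured of 7 listed sex-chromosome genes, was detected on 11 of 11 KO arrays by its better probe and on 2 by its other probe. Its raw signals of 88.9 to 158 lay near background, with changes against WT of -0.44 (adjusted p = 0.065) in KO placebo and -0.46 (adjusted p = 0.12) in KO SAMe livers, so females cannot be excluded. The hepatocyte identity list had a median of 0.15 (SE over members 0.06) where the male-biased list had -0.62. That argues against a share of hepatocytes low enough to give the male-biased fall. The list shares 6 of its 34 measured genes with the acute phase list, which rose, and its SE treats members as independent. Quantile normalization could also hide a fall shared by many bright genes, and how far it would do so here was not tested. A loss of hepatocytes is therefore not excluded. A change of the hormonal control of these genes in the KO stays open as a hypothesis and was not tested.

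Of the 100 measured genes nearest to Mat1a on chromosome 14, 8 changed at least 2-fold in the same direction in both KO groups, more than in 99.3% of 6530 windows of as many neighbouring genes (median 1, highest 9). A stretch of chromosome kept from the strain in which the knockout was made may account for this, as a hypothesis. Loss of SAMe that the treatment replaces is argued against for these genes, since 1 of 10 such genes in KO placebo livers was called back in KO SAMe livers, against 312 of 558 others (exact Fisher test, two-sided p = 0.0066). That test treats genes as independent, which neighbouring genes need not be. It was not rerun with the background block or within the low-background set. For the others called back, treatment and ID letter cannot be told apart. Sequence differences under the probes and true changes of expression were not separated.

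Of 100 splits of the arrays per comparison, 1 gave as many genes as the real split, namely the real split itself, which argues against chance for the 3 counts. A share of 1 in 100 is the lowest that so many splits can give, so chance is not excluded. The splits also cannot tell genotype or treatment from the ID letter or the background set where these go with the groups. In fits of the 2 groups alone the real split gave 4423 genes for KO against WT placebo and the highest other split 3069. For KO SAMe against KO placebo these were 1838 and 1462, and the split with 1462 differed from the real one by 1 array and had the 4 high-background arrays on 1 side. Another split that also differed by 1 array had 3 of these arrays on 1 side, and it gave 1 gene. The count thus fell far when a high-background array, also of letter J, changed sides. For KO SAMe against WT placebo the real split gave 1646 genes and the highest other 744.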

How the results depend on the processing

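The background sets, scaling over the probes past the filter and counting named genes alone were chosen after seeing the data. Over the alternatives, 2078 values of named genes other than Mat1a kept their direction and side of the threshold, 182 lost the call, 8 gained one and 1 reversed, and with single arrays left out these were 2832, 24, 13 and 0. The cause was not tested except where the alternative itself gives fewer arrays, a higher threshold or more genes to adjust for. Main counts were 4359, 2000 and 1904 genes for KO against WT placebo, KO SAMe against KO placebo and KO SAMe against WT placebo, 14, 9 and 13 lists, and 1601 genotype genes called back. Median scaling gave 3355 genes for SAMe against KO placebo, 2677 called back, 9 lists for KO against WT placebo and a Mat1a change under SAMe of -0.11, reversed from 0.12. Scaling over the probes past the filter gave 3492 and 2980 called back. No filter gave 1268 and 1189 genes for the last 2 comparisons, 982 called back and 26, 14 and 22 lists, and the stricter filter 9 lists for KO against WT placebo and 8 for SAMe against WT. The ID letter as a term left 54 genes for KO against WT placebo, 1 gene and 0 lists for SAMe against KO placebo and 1 called back, with Per2 reversed to 0.19 (adjusted p = 0.88). The background block gave 1003 genes for SAMe against KO placebo and 864 called back. Low-background arrays alone gave 1979 and 76 genes for the first 2 comparisons, 70 called back and a Mat1a change under SAMe of -0.0695, and high-background arrays alone, with a lone WT array assumed to vary like the others, 9 lists for KO against WT placebo. A fold of at least 1.5 left 1986, 775 and 766 genes and 566 called back, and an adjusted p under 0.01 left 899 and 904 for the last 2 comparisons and 723 called back. Camera with an estimated correlation called 0, 0 and 0 lists (3, 1 and 4 at an unadjusted p under 0.05), and fry called 23, 9 and 15. With single arrays left out, the counts ranged from 3871 to 4436, 1373 to 2209 and 1213 (without KO SAMe replicate 2) to 2064, genes called back from 1095 to 1744, and lists from 13 to 17, 8 to 10 and 10 to 13. The Mat1a changes ranged from -2.65 to -2.49, 0.01 to 0.18 and -2.51 to -2.44. The BeadChip as a block was not run, because the files used here give no chip. No paired analysis was possible because the labels share no replicate numbers between groups. Signal near background limits genes detected on few arrays.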

Other observations

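The gene counts and list values here belong to lists fixed before the data were examined, and Cela1 was chosen after its values were seen.

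Lists of antioxidant, folate, fatty acid oxidation and methyltransferase genes were not called in KO against WT placebo livers. Of 27 genes of glutathione metabolism and NRF2 targets 13 rose and 4 fell (13 and 5 adjusted over the list alone), with a camera adjusted p = 0.057 and an adjusted p = 0.47 with an estimated correlation. Of 15 folate cycle genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), with a camera adjusted p = 0.25 and an adjusted p = 0.47 with an estimated correlation. Of 30 genes of fatty acid oxidation and PPARA targets 9 rose and 3 fell (9 and 3 adjusted over the list alone), with a camera adjusted p = 0.19 and an adjusted p = 0.56 with an estimated correlation. Of 24 DNA and histone methyltransferases and demethylases, enzymes of which the former use SAMe, 4 rose and 4 fell (4 and 3 adjusted over the list alone), with a camera adjusted p = 0.93 and an adjusted p = 0.95 with an estimated correlation.

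Of the pancreatic acinar list 4 genes were measured, too few for the list test. Cela1 fell by 1.53 in KO against WT placebo livers (adjusted p = 1.8e-06) and rose by 0.86 after SAMe (adjusted p = 0.0076), and Cela2a fell by 1.01 (adjusted p = 0.00016) and rose by 1.37 (adjusted p = 0.00041). Amy2a5 and Cpb1, which code for abundant pancreatic enzymes, had changes of -0.13 (adjusted p = 0.48) and 0.05 (adjusted p = 0.68) in KO against WT placebo livers. With the background set as a block the change of Cela1 after SAMe was 0.54 (adjusted p = 0.16).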
